A study of Homo sapiens with 39 samples.

How the data were processed

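Values were taken from the sample tables of 39 arrays as deposited: 9 Affymetrix U133A, 12 Affymetrix U133 Plus 2 and 18 Illumina BeadChip arrays. Raw scans were not used. For the 21 Affymetrix samples the authors deposited intensity values on a linear scale made with GCRMA (a background correction, quantile normalization and summary of probe sets), per the submitters' processing notes, and its version is not given in the sources used here. For the 12 transfected Illumina samples the intensity values were deposited on a linear scale and share one distribution, and how they were processed before deposit is not given in the sources used here. For the 6 untransfected Illumina samples the values were deposited as log2 values already, with the base inferred from their range, and their processing is not given in the sources used here. All linear intensities were turned into log2 values here. The 2 Illumina sets were normalized separately before deposit, so no comparison was made between them. The comparison of OF with untransfected hypoxic cells on Illumina, which had been planned, was left out for this reason, since the set, the transfection and the sample numbers change together.

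Gene names came from the annotation tables supplied with the data, with symbols updated through the Entrez number. Of 22283 U133A, 54675 U133 Plus 2 and 47293 Illumina probes, 19065, 41091 and 18468 had a single gene name. Several names were given for 1043, 1801 and 0 probes, no name for 2107, 11721 and 28825, and 68, 62 and 0 were control probes. The probe with the highest mean stood for each gene, which left 11963, 19775 and 16225 genes. A gene was tested if it was brighter than the 40th percentile of all its array set in at least 3 arrays on Affymetrix, or 2 on Illumina, which left 7298, 12145 and 11175 tested genes. Genome positions were not used, since the probes carry identifiers only.

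All arrays of a type (9, 12 and 18) were fitted together, with 1 estimate of the spread per gene, with R 4.3.3 and limma 3.58.1 (linear models per gene, with the prior variance following the mean level), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05 on the adjusted p. Every adjusted p of a gene in the report is from this moderated t test, with 3 arrays per group on Affymetrix and for transfected Illumina samples, and 2 for untransfected Illumina samples. The test assumes similar spread in all groups of an array type, and on Illumina also in both sets, since groups of 2 give little information on the spread alone. The comparisons were hypoxia and DMOG with normoxia and with each other, each siRNA with OF, HIF1 with HIF2 siRNA, and the interaction (the change with HIF12 siRNA minus the sum of the single changes). These and the rules below were written down before the data were examined.

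Gene lists were fixed from general knowledge of the genes: glycolysis and glucose uptake, 2-oxoglutarate dioxygenases, angiogenic and secreted hypoxia targets, hypoxia targets for pH, stress and cell death, HIF pathway components, DNA replication and S phase, mitosis, estrogen response, integrated stress and unfolded protein response, nuclear-encoded oxidative phosphorylation, ribosome biogenesis, cholesterol synthesis, interferon response, heat shock, p53 targets, mesenchymal and basal cell markers, and leukocyte and endothelial markers. EGLN1 and EGLN3 stand in the dioxygenase and HIF pathway lists, and CITED2 in the HIF pathway list and the list for pH, stress and cell death. Lists were tested with camera from limma with a correlation of 0.01 between genes, and again with the correlation estimated from the data. A rotation test (fry) was run as an alternative. Members were counted as changed over all tested genes and, separately, adjusted over the list alone.

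Genes were named by a rule: HIF1A and EPAS1, the 8 largest increases and 6 largest decreases among called genes whose groups do not overlap, and up to 3 called members of each list by size of change. For hypoxia against DMOG, HIF1 against HIF2 siRNA and the interaction, up to 5 in each direction were taken. For the hypoxia genes under siRNA, the 5 largest decreases were taken for each siRNA, and the 5 genes with the largest hypoxic increase that did not pass with HIF12 siRNA. Genes named outside the rule were chosen after their values were seen, and the text says so there.

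Genes changed at least 1 log2 unit in hypoxia on U133A, with an adjusted p past the threshold, were followed in the siRNA comparisons by probe set on U133 Plus 2 and by symbol on Illumina. Adjusted p-values in that part are over the 7298 genes tested in hypoxia, or the 6442 of them tested on Illumina. The overlap of comparisons that share control arrays was set against 50 simulations of unchanged groups. All arrays were simulated there, the shared controls included, with genes independent of each other. Whether sample numbers pair arrays across groups was read from the correlation of deviations from group means. Arrays of the same number correlated from 0.518 to 0.831 on U133 Plus 2, and from 0.298 to 0.517 (HIF1 siRNA) and 0.274 to 0.491 (HIF12 siRNA) on Illumina. There the number was treated as a pairing and the fit with the number as a block is given beside the counts and list results that it changes most. It was not run for the direct differences between siRNAs among hypoxia genes. On U133A the values went from -0.242 to 0.481, and the block was used only as an alternative.

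A self-test added known changes to 100 simulated genes per size. At 1 and 2 log2 units the U133A fit of hypoxia found 47% and 96% and called 7 unchanged genes. The U133 Plus 2 fit of HIF1 siRNA found 52% and 91% with 7 unchanged genes called, and the Illumina fit of hypoxia 94% and 100% with 5. Where arrays of the same number were made to shift together, the U133 Plus 2 fit found 25% and 81%, and 54% and 91% with the block. Other divisions of the samples into groups of the same sizes were fitted in the same way.

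The alternatives were no filter and a 60th percentile filter, quantile normalization, arrays centred on their median, a constant prior variance, the mean of all probe sets of a gene, every probe set, only the groups compared, a stricter adjusted p of 0.01, a change of at least 1 log2 unit, other limits for the hypoxia list, the replicate block, and leaving out each array in turn. For the hypoxia list all U133 Plus 2 arrays of a sample number were left out together instead. Chosen after seeing the data were fits without hypoxia 1 and DMOG 1, fits without the 4 U133 Plus 2 arrays numbered 1, the choice of the hypoxia list without hypoxia 1 and DMOG 1, and hypoxia against DMOG on Illumina.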

Results

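Gene expression was measured in MCF7 cells, an established human breast cancer line that expresses the estrogen receptor, on 39 arrays of 3 kinds. Cells were kept at 21% oxygen (normoxia), at 1% oxygen for 16 h (hypoxia), or at 21% oxygen with 2 mM dimethyloxalylglycine (DMOG) for 16 h. DMOG is a cell-permeable compound that inhibits 2-oxoglutarate-dependent dioxygenases, the enzyme class that includes the prolyl hydroxylases marking hypoxia-inducible factor (HIF) for degradation. In other cells, all at 1% oxygen, oligofectamine alone (OF) was compared with small interfering RNA against HIF1A (HIF1 siRNA), against EPAS1, which encodes HIF-2α (HIF2 siRNA), or against both (HIF12 siRNA). No sample received a control siRNA, and no transfected cells were kept at 21% oxygen. Changes against OF can therefore include effects of an siRNA other than the loss of its target. Affymetrix U133A arrays held the 3 normoxia, 3 hypoxia and 3 DMOG samples, and Affymetrix U133 Plus 2 arrays held 3 samples of each transfected group. Illumina BeadChips held samples 2 and 3 of normoxia, hypoxia and DMOG again, and 3 further samples of each transfected group. Median levels of the arrays were 5.23 to 5.43 log2 units on U133A, 3.73 to 3.97 on U133 Plus 2, 6.79 in the untransfected Illumina set and 5.59 to 5.60 in the transfected one. The small number of arrays per group limits the precision of every value below. Errors are standard errors (SE) of the limma fit with n = 3 per group on the Affymetrix arrays, and p-values are adjusted over all tested genes unless stated otherwise. The p-values measure spread between the 3 samples of a condition, which the series text calls independent. For every called gene named on the Affymetrix arrays, the 3 arrays of one group lay above all 3 arrays of the other.

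The siRNA targets were examined first. HIF1A read 11.90, 12.20 and 12.09 log2 units in the 3 OF samples on U133 Plus 2, and 8.66, 10.54 and 10.01 with HIF1 siRNA. It read 11.99, 12.47 and 12.30 with HIF2 siRNA, and 9.12, 9.69 and 10.09 with HIF12 siRNA. HIF1A was 5.02-fold lower with HIF1 siRNA (log2 change -2.33 ± 0.41, adjusted p = 0.00866) and 5.41-fold lower with HIF12 siRNA (-2.43 ± 0.41, adjusted p = 0.0067). With HIF2 siRNA its change was 0.19 ± 0.41 (adjusted p = 1). EPAS1 read 10.56, 8.76 and 8.55 in OF, and 10.72, 9.05 and 8.87 with HIF1 siRNA. It read 5.05, 5.47 and 5.21 with HIF2 siRNA, and 6.17, 5.18 and 4.75 with HIF12 siRNA. The EPAS1 level was 16.5-fold lower with HIF2 siRNA (-4.05 ± 0.61), which missed the threshold over all genes (adjusted p = 0.143) and passed with the replicate number as a block (adjusted p = 0.00261). With HIF12 siRNA it was 15.2-fold lower (-3.92 ± 0.61, adjusted p = 0.00463). On Illumina, HIF1A changed by -0.88 ± 0.16 with HIF1 siRNA (adjusted p = 0.000668) and by -0.57 ± 0.16 with HIF12 siRNA (adjusted p = 0.0173). EPAS1 was dim there, at 5.62, 5.88 and 5.77 log2 units in OF, and its values of -0.28 ± 0.15 (HIF2 siRNA, adjusted p = 0.237) and -0.32 ± 0.15 (HIF12 siRNA, adjusted p = 0.145) did not pass. In untransfected cells on U133A, EPAS1 rose 2.22-fold in hypoxia (1.15 ± 0.21, adjusted p = 0.00867) and 3.39-fold with DMOG (1.76 ± 0.21, adjusted p = 0.000662). HIF1A changed by -1.19 ± 0.28 with DMOG (adjusted p = 0.0354), and its value of -0.89 ± 0.28 in hypoxia did not pass (adjusted p = 0.0946). On Illumina, with samples 2 and 3 of the same, HIF1A fell both in hypoxia (-0.96 ± 0.20, adjusted p = 0.0015) and with DMOG (-1.09 ± 0.20, adjusted p = 0.000394). There EPAS1 rose with DMOG (0.60 ± 0.18, adjusted p = 0.0153) and did not pass in hypoxia (0.21 ± 0.18, adjusted p = 0.439).

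**Figure D1:**
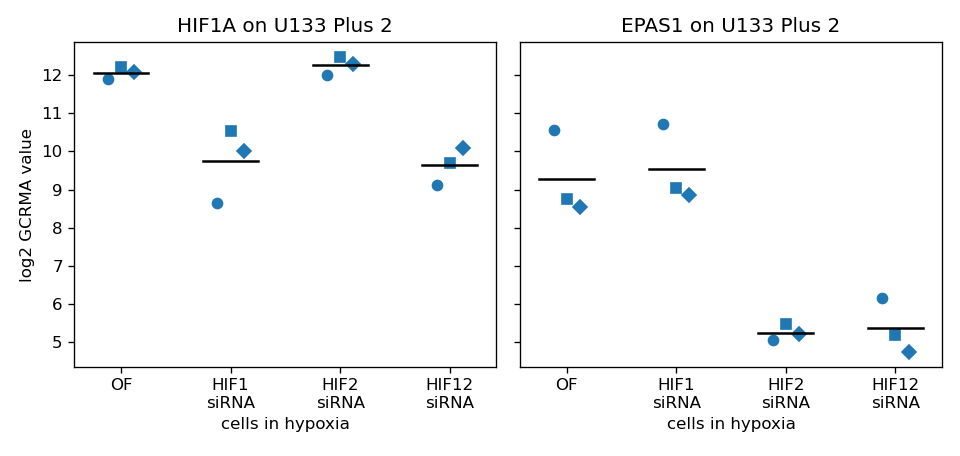
Levels of HIF1A (left) and EPAS1 (right) on the U133 Plus 2 arrays, on the vertical axis in log2 units, for the 4 groups of transfected hypoxic cells. Circles, squares and diamonds are samples 1, 2 and 3 and the bars are group means. HIF1A lies lower in the HIF1 and HIF12 siRNA groups and EPAS1 in the HIF2 and HIF12 siRNA groups, with the EPAS1 value of 10.56 in OF sample 1 above the 8.76 and 8.55 of the other OF samples.

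The comparison of hypoxia with normoxia asked which transcripts change after 16 h at 1% oxygen. The largest increase on U133A was in ADM, which encodes the vasodilator peptide adrenomedullin, at 93.4-fold (6.55 ± 0.64 log2 units, adjusted p = 3e-04). TMEM45A rose 77.7-fold (6.28 ± 0.47), EGFR, a growth factor receptor, 49.5-fold (5.63 ± 0.52) and IGFBP3, which binds insulin-like growth factors, 42.3-fold (5.40 ± 0.37). FOS, a subunit of the AP-1 transcription factor, rose 39.3-fold, FAM13A 35.6-fold, the stress-responsive gene NDRG1 29.7-fold and GJA1, which encodes the gap junction protein connexin 43, 29.1-fold. The largest decrease was in CTPS1, a CTP synthase, which was 7.85-fold lower (-2.97 ± 0.42, adjusted p = 0.00274). TAF9B, CORO1A, LARP4 and ABCF2 were 5.11-, 5.01-, 4.91- and 4.63-fold lower, and ODC1, the first enzyme of polyamine synthesis, was 4.32-fold lower.

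Among the gene lists fixed in advance, 19 of 24 tested genes of glycolysis and glucose uptake rose and none fell (camera adjusted p = 2.75e-25). The aldolase ALDOC rose 25.4-fold, the enolase ENO2 22.5-fold and the phosphoglucomutase PGM1 9.72-fold. Of 15 angiogenic and secreted targets 11 rose (adjusted p = 5.96e-14), among them LOXL2, a lysyl oxidase family member, by 22.9-fold. Of 15 genes for pH, stress and cell death 10 rose (adjusted p = 1.57e-16), including INSIG2, a regulator of sterol synthesis, at 11.6-fold and the mitophagy receptor BNIP3L at 9.64-fold. Of 21 dioxygenases 9 rose, led by the prolyl hydroxylase EGLN3 at 15.3-fold, with the collagen prolyl hydroxylase subunit P4HA2 at 7.47-fold and the histone demethylase KDM3A at 7.01-fold. These 4 lists also passed with an estimated correlation between genes (adjusted p = 0.00404, 0.00154, 0.00154 and 0.0412 in that order). Adjusted over the list alone, 22, 11, 11 and 10 members rose.

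In the HIF pathway list 4 of 10 members rose (adjusted p = 0.00468, and adjusted p = 0.43 with an estimated correlation), including the coactivator-binding CITED2 at 5.62-fold and EGLN1 at 3.66-fold. In the list for integrated stress and the unfolded protein response 4 of 16 rose and 1 fell (adjusted p = 0.000591, and adjusted p = 0.0564 with an estimated correlation). Among these the lipoprotein receptor VLDLR rose 12.7-fold and the transcription factor ATF3 3.02-fold, while SDF2L1, a component of an endoplasmic reticulum chaperone complex, was 3.19-fold lower. Of 15 ribosome biogenesis genes 5 fell (adjusted p = 0.00154, and adjusted p = 0.346 with an estimated correlation), among them RRP12 with -1.27 ± 0.29 and NOP16 with -1.07 ± 0.23. Of 9 heat shock genes 4 fell (adjusted p = 4e-04, and adjusted p = 0.365 with an estimated correlation), including HSPH1, 3.89-fold lower, and DNAJA1, 2.31-fold lower. Of 32 nuclear genes of oxidative phosphorylation 3 fell, namely CYCS, CYC1 and ATP5F1A with -1.25 ± 0.20, -0.82 ± 0.13 and -0.79 ± 0.21 (adjusted p = 0.00154, and adjusted p = 0.433 with an estimated correlation). None of 28 genes of DNA replication and S phase was called, with a list median of -0.37 (adjusted p = 0.001, and adjusted p = 0.43 with an estimated correlation). Of 24 mitosis genes the anaphase activator CDC20 fell, 2.60-fold (adjusted p = 0.0091, and adjusted p = 0.43 with an estimated correlation). Of 12 cholesterol synthesis genes none was called, with a median of 0.31 (adjusted p = 0.0126, and adjusted p = 0.43 with an estimated correlation). The estrogen response list (1 of 18 fell, the receptor tyrosine kinase RET), p53 targets (1 of 9 rose, GDF15), interferon response (0 of 8) and mesenchymal and basal markers (0 of 5) did not pass as lists. Of the leukocyte and endothelial markers only 1 was bright enough to test on each Affymetrix array, and it was called in no comparison.

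In total, 328 genes were higher and 241 lower in hypoxia among 7298 tested, 260 and 141 of them by at least 1 log2 unit. The log2 ratio of the 3' to the 5' control probe set of beta-actin (ACTB), a measure of RNA integrity, was 2.34 on hypoxia array 1 and 1.73 on DMOG array 1, against 0.60 to 1.07 on the other U133A arrays. The same ratio of GAPDH was 1.01 on hypoxia array 1 but 0.25 on DMOG array 1, within the 0.06 to 0.38 of the others. Without those 2 arrays 763 genes were called in hypoxia, with 21 glycolysis genes higher, 4 mitosis genes lower and 1 higher, and an adjusted p = 0.185 with an estimated correlation for the dioxygenases. Without normoxia 2, normoxia 3, hypoxia 1, hypoxia 2 or hypoxia 3, the number of called genes was 347, 287, 343, 308 and 299.

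The comparison of DMOG with normoxia asked how dioxygenase inhibition in normal oxygen changes the same transcripts. ADM rose 117-fold (6.87 ± 0.64 log2 units, adjusted p = 0.000171), TMEM45A 94.1-fold (6.56 ± 0.47), EGFR 74.2-fold (6.21 ± 0.52) and GJA1 55.2-fold (5.79 ± 0.28). NDRG1 rose 49.5-fold, FAM13A 49.2-fold, IGFBP3 41.8-fold and ITPR1, an intracellular calcium channel, 38.6-fold. The actin-binding CORO1A fell most, by 5.08-fold (-2.35 ± 0.26, adjusted p = 0.000552). It was followed by PIK3R3, a regulatory subunit of phosphoinositide 3-kinase, TAF9B, SPAG1, CTPS1 and the sodium channel subunit SCNN1A, which were 4.39-, 4.29-, 4.26-, 4.23- and 4.01-fold lower. SPAG1 did not change on Illumina past the threshold (0.19, adjusted p = 0.49).

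With DMOG, 20 of 24 glycolysis genes rose (camera adjusted p = 2.27e-26), with ENO2 at 30.8-fold, ALDOC at 21.9-fold and PGM1 at 14.5-fold. Of 15 angiogenic and secreted targets 11 rose, LOXL2 by 23.9-fold, and of 15 genes for pH, stress and cell death 12 rose, INSIG2 by 16.9-fold and BNIP3L by 11.4-fold. These 3 lists passed with an estimated correlation as well (adjusted p = 0.0036, 0.00244 and 0.00209). Of 21 dioxygenases 8 rose (adjusted p = 3.26e-07, and adjusted p = 0.0654 with an estimated correlation), EGLN3 by 19.5-fold, P4HA2 by 9.85-fold and KDM3A by 9.80-fold. The HIF pathway list had 4 of 10 members higher, among them CITED2 at 6.83-fold and EGLN1 at 5.95-fold, and HIF1A lower (adjusted p = 0.000225, and adjusted p = 0.256 with an estimated correlation). Of 28 genes of DNA replication and S phase 7 fell, and 15 fell adjusted over the list alone (adjusted p = 9.89e-09, and adjusted p = 0.256 with an estimated correlation). MCM10, which helps activate the replicative helicase, was 3.55-fold lower, cyclin E1 (CCNE1) 1.73-fold and the flap endonuclease FEN1 1.71-fold. Of 18 estrogen response genes 3 fell, RET by 3.48-fold, the chemokine CXCL12 by 3.45-fold and the estrogen receptor ESR1 by 1.76-fold, and 1 rose (list adjusted p = 0.358). Of 9 p53 targets 2 rose, GDF15 by 3.02-fold and GADD45A by 2.78-fold (adjusted p = 0.00551, and adjusted p = 0.169 with an estimated correlation). In the integrated stress list 5 of 16 rose and 1 fell (adjusted p = 0.0579), with ATF3 at 10.8-fold and VLDLR at 10.6-fold higher.

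In oxidative phosphorylation 2 of 32 genes fell, CYC1 and ATP5MC1 (adjusted p = 0.0252, and adjusted p = 0.681 with an estimated correlation). In ribosome biogenesis NOP2 fell and MYC rose, of 15 (adjusted p = 0.0403, and adjusted p = 0.454 with an estimated correlation). No heat shock gene of 9 was called, with a median of -0.39 (adjusted p = 0.00183, and adjusted p = 0.374 with an estimated correlation), and mitosis, cholesterol synthesis, interferon and mesenchymal lists did not pass and held no called gene. In all, 322 genes were higher and 210 lower with DMOG, 259 and 101 of them by at least 1 log2 unit. Without hypoxia array 1 and DMOG array 1, whose beta-actin ratios stood apart, 1427 genes were called, 31.6% of them higher, and 21 S phase genes, 10 oxidative phosphorylation genes, 7 heat shock genes, 7 ribosome biogenesis genes and 3 mitosis genes fell. In the integrated stress list 5 then rose and 3 fell, in the estrogen list 2 rose and 4 fell, and 1 gene each rose in the cholesterol and mesenchymal lists and fell in the interferon list. Without normoxia 3, DMOG 1, DMOG 2 or DMOG 3 the number of called genes was 283, 965, 291 and 280.

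The treatments were then compared with each other. No gene passed between hypoxia and DMOG on U133A in limma (447 had an unadjusted p under 0.05). Among genes called against normoxia, 348 were called under both treatments in the same direction, 236 higher and 112 lower, and none in opposite directions. Independent lists of these sizes would share 14.5 higher and 6.9 lower genes. Across genes, which are not independent replicates, the changes correlated with r = 0.857 and had a covariance of 0.341. In simulations of unchanged groups with simulated shared controls these were 0.501 and 0.041. The simulated r follows from the shared control and the equal group sizes alone. The 3 normoxia arrays could not be split into parts of at least 2, so part of the excess of shared genes over independent lists can come from the shared controls. How much these 3 arrays themselves contribute was not measured. For the 348 shared genes the median 95% interval of the difference extended 0.50 log2 units to either side, and for 261 the whole interval lay within 1 log2 unit, so smaller differences were not excluded. None of the lists held a called gene in this comparison. The genes of S phase had a median difference of 0.27 (camera adjusted p = 2.11e-05, and adjusted p = 0.437 with an estimated correlation) and those for pH, stress and cell death -0.43 (adjusted p = 0.00137, and adjusted p = 0.189 with an estimated correlation). Mitosis genes had a median of -0.33 (adjusted p = 0.00137), cholesterol synthesis genes 0.27 (adjusted p = 0.00821), HIF pathway genes -0.32 (adjusted p = 0.0272) and p53 targets -0.31 (adjusted p = 0.0329), each with an adjusted p = 0.437 with an estimated correlation. Glycolysis genes (-0.12, adjusted p = 0.04) and ribosome biogenesis genes (-0.15, adjusted p = 0.0399) also had 0.437 there, and the other lists did not pass. Without hypoxia 1 and DMOG 1 the mitosis (median -0.01, adjusted p = 0.201), cholesterol (0.11, adjusted p = 0.494), HIF pathway (0.05, adjusted p = 0.311) and ribosome lists (-0.06, adjusted p = 0.354) no longer passed. The S phase list (0.54, adjusted p = 6.83e-09), the list for pH, stress and cell death (adjusted p = 0.000423), glycolysis (adjusted p = 0.00266) and p53 targets (adjusted p = 0.0301) still did, though not with an estimated correlation (adjusted p = 0.567, 0.318, 0.567 and 0.567). Without DMOG 1, 9 genes were called. On Illumina, with samples 2 and 3 of the same, 527 genes were higher and 372 lower in hypoxia than with DMOG, 53 of them by at least 1 log2 unit, in a comparison chosen after seeing the data. Of 544 such genes tested on U133A, 490 had the same sign there.

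HIF1 siRNA was compared with OF, which held no siRNA, to ask which transcripts of hypoxic cells depend on HIF-1α. GJA1 fell most on U133 Plus 2, by 13.1-fold (-3.71 ± 0.31 log2 units, adjusted p = 0.000902). COXFA4L2 (formerly NDUFA4L2), related to a subunit of cytochrome c oxidase, was 12-fold lower (-3.58 ± 0.60), and the collagen crosslinking enzyme LOX 9.37-fold (-3.23 ± 0.56). TMEM45A was 8.18-fold lower, PFKFB4, which controls the glycolytic regulator fructose-2,6-bisphosphate, 7.91-fold and the ubiquitin ligase RNF183 7.61-fold. The largest increases were in the reductase AKR1B10 (6.16-fold, 2.62 ± 0.60, adjusted p = 0.0294), heme oxygenase HMOX1 (5.26-fold, 2.40 ± 0.31), the cell cycle phosphatase CDC25A (4.70-fold) and the hyaluronan synthase HAS3 (4.46-fold). SLC25A33, a mitochondrial carrier, MARS2, TAF9B and the phosphatase PHLPP2 followed at 4.37-, 4.10-, 3.91- and 3.87-fold. In the separate Illumina samples GJA1 changed by -0.16 (adjusted p = 0.461) and CDC25A by -0.03 (adjusted p = 0.914), neither past the threshold, while COXFA4L2, LOX, TMEM45A, PFKFB4 and RNF183 fell with -2.78, -2.52, -2.66, -2.01 and -2.30.

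Of 24 glycolysis genes 17 fell with HIF1 siRNA and none rose (camera adjusted p = 1.6e-22, and adjusted p = 0.0175 with an estimated correlation), ENO2 by 5.24-fold and ALDOC by 5.20-fold. With the replicate number as a block 22 fell and 1 rose, and the estimated-correlation p of this list was 0.126, past no threshold. Of 25 dioxygenases 7 fell, EGLN3 by 4.87-fold, EGLN1 by 3.00-fold and P4HA2 by 2.88-fold. Of 16 angiogenic and secreted targets 7 fell, IGFBP3 by 6.38-fold and the lipoprotein lipase inhibitor ANGPTL4 by 3.58-fold. Of 16 genes for pH, stress and cell death 6 fell, BNIP3L by 4.12-fold and BNIP3, a related mitophagy receptor, by 3.97-fold, and HMOX1 rose. These 3 lists had camera adjusted p-values of 2.28e-07, 6.25e-07 and 1.91e-08, each with an adjusted p = 0.0648 with an estimated correlation. With the block, 12, 10 and 14 of their members fell. The HIF pathway list, which holds HIF1A itself, had 4 of 11 lower (adjusted p = 0.000205, and adjusted p = 0.243 with an estimated correlation), among them ARNT, the dimerization partner of both HIF-α subunits, by 3.35-fold.

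Of 16 ribosome biogenesis genes 4 rose with HIF1 siRNA, NOP16 by 2.19-fold, NOP2 by 2.15-fold and POLR1C by 2.05-fold (adjusted p = 6.58e-05, and adjusted p = 0.0372 with an estimated correlation). With the block 8 rose and the adjusted p = 0.192 with an estimated correlation. The replicative helicase subunit MCM3 was the 1 of 28 S phase genes that rose (list adjusted p = 0.00434, and adjusted p = 0.511 with an estimated correlation), and HSPH1 the 1 of 9 heat shock genes (adjusted p = 0.03, and adjusted p = 0.428 with an estimated correlation). The proliferation antigen gene MKI67 rose 1.53-fold as the 1 called gene of the mitosis list. In the integrated stress list SDF2L1 and the asparagine synthetase ASNS rose, 2 of 18 (adjusted p = 0.076, and 0.0456 with the block, where the estimated correlation gave an adjusted p = 0.397). In oxidative phosphorylation 3 of 32 rose, including NDUFA9 and CYC1, and COX5A fell. In cholesterol synthesis HMGCS1 rose, 1 of 12, in the p53 list FAS rose and TP53INP1 fell 3.09-fold, and in the estrogen list KRT13 fell. The interferon (0 of 16 called, adjusted p = 0.0723, and 0.0251 with the block, where the estimated correlation gave an adjusted p = 0.397) and mesenchymal lists (0 of 6) held no called gene. With the block 12 S phase genes rose and 2 fell, 4 mitosis genes rose and 1 fell, and 9 integrated stress genes rose and 2 fell. In oxidative phosphorylation 7 then rose and 2 fell, in heat shock 5 rose, in cholesterol synthesis 3 rose, in the p53 list 3 rose and 1 fell, in the estrogen list 4 rose and 7 fell, in the interferon list 5 fell and in the mesenchymal list 1 rose. Without the 4 arrays numbered 1, 10 genes for pH, stress and cell death fell, 3 estrogen response genes rose and 3 fell, 3 heat shock genes rose and no mitosis gene was called in limma. In that fit the heat shock list did not pass (adjusted p = 0.0652), nor did glycolysis and ribosome biogenesis with an estimated correlation (adjusted p = 0.157 each). In all, 518 genes were higher and 315 lower among 12145, 148 and 166 of them by at least 1 log2 unit. With the replicate number as a block 3287 genes were called, and without OF 1, OF 2, OF 3, HIF1 siRNA 1 or HIF1 siRNA 3 the number was 399, 486, 322, 477 and 414. The U133 Plus 2 arrays numbered 1 differed together from the others in every group, and without these 4 arrays 1336 genes were called.

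HIF2 siRNA was compared with OF to ask the same of HIF-2α. On U133 Plus 2, 3 genes passed. STRADB, a pseudokinase that binds the kinase LKB1, rose 4.06-fold (2.02 ± 0.23 log2 units, adjusted p = 0.0227) and also on Illumina (1.75, adjusted p = 2.4e-09). The microRNA-processing enzyme DICER1 rose 2.90-fold (1.54 ± 0.15, adjusted p = 0.0137), with 0.18 on Illumina (adjusted p = 0.345), and the keratin gene KRT13 fell 1.85-fold (-0.88 ± 0.11, adjusted p = 0.0424). With the replicate number as a block 32 genes were called, EPAS1 among them. No member of the glycolysis (24), dioxygenase (25), angiogenic (16) and pH, stress and cell death (16) lists was called, with medians of 0.02, -0.02, -0.11 and 0.03 and no list past the threshold. KRT13 was the 1 called gene of 20 in the estrogen response list, which did not pass. The HIF pathway, S phase, integrated stress, oxidative phosphorylation, ribosome, cholesterol, heat shock, p53 and mesenchymal lists did not pass either. Of 16 interferon response genes none was called over all genes, and 3 fell adjusted over the list alone. With the block 3 fell over all genes and 11 over the list alone. The list median was -0.75 (camera adjusted p = 5.44e-16, and adjusted p = 0.135 with an estimated correlation). The mitosis list had a median of 0.25 and no called gene of 24 (adjusted p = 1.05e-08, and adjusted p = 0.484 with an estimated correlation). An unadjusted p under 0.05 was found for 302 of 12145 genes, fewer than the share of 0.05 that unchanged genes would give on average. Without OF 1 or OF 3 the number of called genes was 1, and without OF 2 or any 1 HIF2 siRNA array it was 0.

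HIF12 siRNA was compared with OF to ask which transcripts depend on either subunit. GJA1 was 19.8-fold lower (-4.31 ± 0.31 log2 units, adjusted p = 0.000268), TMEM45A 17.5-fold (-4.13 ± 0.30) and IGFBP3 15.4-fold (-3.95 ± 0.44). LOC154761, a non-coding RNA locus, was 15.1-fold lower and RNF183 13.4-fold. AKR1B10 rose 5.43-fold (2.44 ± 0.60, adjusted p = 0.0375), the RNA-binding protein gene RBPMS2 4.35-fold (2.12 ± 0.26), CDC25A 4.25-fold and SLC25A33 3.8-fold. The phosphatases PPM1E and PHLPP2 rose 3.77- and 3.68-fold, TAF9B 3.74-fold and DICER1 3.67-fold. On Illumina GJA1 again did not pass (-0.03, adjusted p = 0.922), and neither did DICER1 (0.16, adjusted p = 0.383).

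Of 24 glycolysis genes 17 fell, including the pyruvate dehydrogenase kinase PDK1 (7.47-fold), PFKFB4 (6.89-fold) and ENO2 (6.49-fold). Of 25 dioxygenases 9 fell, EGLN3 by 9.32-fold, EGLN1 by 4.10-fold and P4HA2 by 3.31-fold. Of 16 angiogenic and secreted targets 8 fell, LOX by 10.2-fold and LOXL2 by 9.09-fold. Of 16 genes for pH, stress and cell death 9 fell and 1 rose, with INSIG2 5.41-fold, BNIP3L 4.55-fold and CITED2 3.91-fold lower. The camera adjusted p-values of these 4 lists were 2.52e-24, 8.94e-09, 1.33e-09 and 3.24e-10, and with an estimated correlation 0.0137, 0.0406, 0.04 and 0.0406. In the fit with the block the estimated-correlation p-values were 0.107, 0.107, 0.118 and 0.107, while 22, 13, 11 and 13 members fell. Of 11 HIF pathway genes, which include both targets, 6 fell (adjusted p = 4.49e-07, and adjusted p = 0.0903 with an estimated correlation). Of 16 ribosome biogenesis genes 3 rose, NOP2, NOP16 and POLR1B (adjusted p = 0.000743, and adjusted p = 0.0406 with an estimated correlation, or 0.254 with the block). The transcription factor IRF7 fell 2.66-fold as the 1 called member of 16 in the interferon list (adjusted p = 0.00328, and adjusted p = 0.403 with an estimated correlation).

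In the integrated stress list 3 of 18 rose with HIF12 siRNA, SDF2L1, CHAC1 and ASNS (adjusted p = 0.0226, and adjusted p = 0.276 with an estimated correlation), and HSPH1 rose in the heat shock list, 1 of 9 (adjusted p = 0.0082, and adjusted p = 0.299 with an estimated correlation). The apoptosis inhibitor BIRC5 rose 2.83-fold as 1 of 24 mitosis genes (list adjusted p = 0.0483, or 0.0554 with the block, and adjusted p = 0.666 with an estimated correlation). CCNE1 and MCM3 rose in the S phase list (2 of 28), HMGCS1 and SQLE in cholesterol synthesis (2 of 12), and NDUFA9, CYC1 and NDUFS3 among 4 of 32 in oxidative phosphorylation. None of these 3 lists passed. CCNG1 rose and TP53INP1 fell in the p53 list, RET rose and KRT13 fell in the estrogen list, and no mesenchymal marker of 6 was called. With the block 6 S phase genes rose and 3 fell, 5 mitosis genes rose, 8 integrated stress genes rose and 2 fell, 8 ribosome biogenesis genes rose, and 5 heat shock genes rose. In oxidative phosphorylation 8 then rose and 2 fell, in cholesterol synthesis 3 rose and 2 fell, in the p53 list 2 rose and 2 fell, in the estrogen list 3 rose and 5 fell, in the interferon list 7 fell and in the mesenchymal list 1 fell. Without the 4 arrays numbered 1 the mitosis (adjusted p = 0.0509) and integrated stress lists (adjusted p = 0.0644) did not pass, and S phase (adjusted p = 0.0141) and oxidative phosphorylation (adjusted p = 0.0463) did, each with an adjusted p = 0.61 with an estimated correlation. With an estimated correlation the glycolysis, dioxygenase, angiogenic and pH, stress and cell death lists then had an adjusted p of 0.13, 0.13, 0.13 and 0.241, and ribosome biogenesis 0.136. In all, 428 genes were higher and 393 lower, 99 and 229 of them by at least 1 log2 unit. With the replicate block 3127 genes were called, without the 4 arrays numbered 1 the number was 1362, and without OF 1, OF 2, OF 3 or HIF12 siRNA 2 it was 487, 461, 368 and 506. Of the genes called with HIF1 and with HIF12 siRNA, 572 were shared in direction (326 higher, 246 lower, against 18.3 and 10.2 for independent lists). The correlation of the changes was 0.866, against 0.498 in simulations with simulated shared controls, and the covariance 0.195 against 0.043. The 3 OF arrays could not be split into parts of at least 2, so part of the excess of shared genes over independent lists can come from them.

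**Figure D2:**
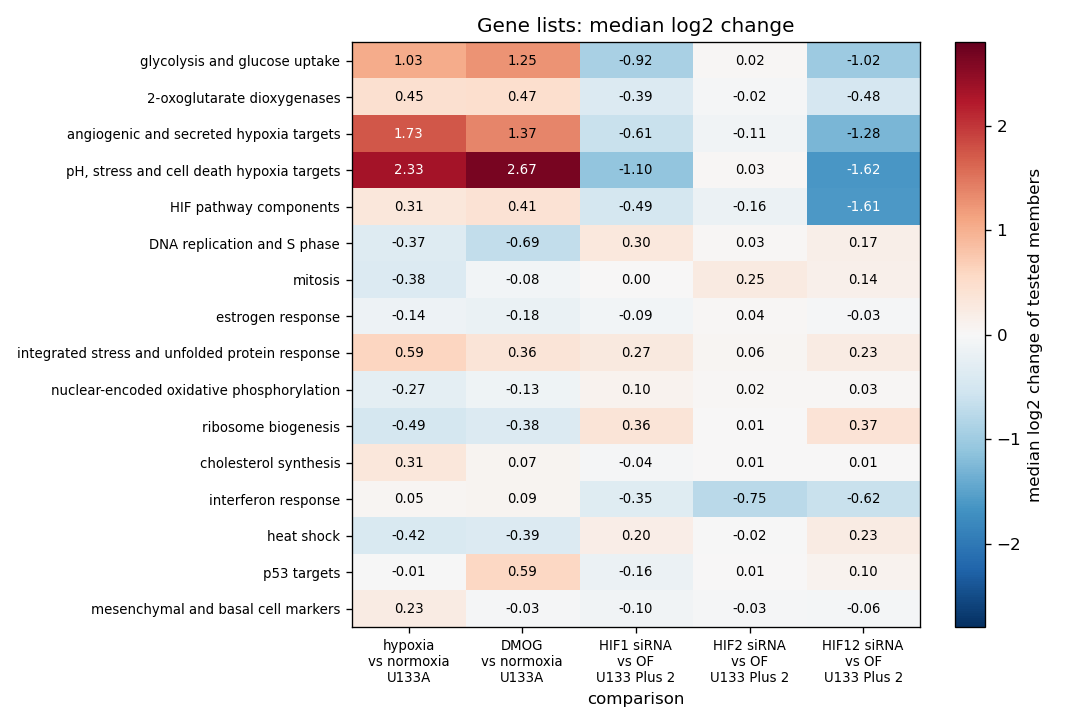
Median log2 change of the tested members of each gene list (rows) in the 5 main comparisons on Affymetrix arrays (columns), as a color and a printed value, red for higher and blue for lower. Glycolysis genes had medians of 1.03 in hypoxia and 1.25 with DMOG, and of -0.92, 0.02 and -1.02 with HIF1, HIF2 and HIF12 siRNA.

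The single siRNA treatments were compared directly. EPAS1 was 19.8-fold higher with HIF1 siRNA than with HIF2 siRNA (4.31 ± 0.61 log2 units, adjusted p = 0.00355), and HIF1A 5.72-fold lower (-2.52 ± 0.41, adjusted p = 0.00662). HAS3 was 7.68-fold higher, the sulfate transporter SLC26A2 5.59-fold, HYCC1 4.10-fold and the inhibin subunit INHBE 4.03-fold. LOX was 12.4-fold lower (-3.63 ± 0.56, adjusted p = 0.00543), COXFA4L2 9.54-fold, PFKFB4 9.15-fold, GJA1 8.93-fold and RNF183 8.70-fold. The difference in the glycolysis list passed, with 17 of 24 genes lower under HIF1 siRNA (camera adjusted p = 4.02e-24, and adjusted p = 0.0141 with an estimated correlation, or 0.112 with the block). In ribosome biogenesis 4 of 16 genes were higher (adjusted p = 1.22e-05, and adjusted p = 0.023 with an estimated correlation, or 0.235 with the block). Of 25 dioxygenases 9 were lower, of 16 angiogenic and secreted targets 6 lower and 1 higher, and of 16 genes for pH, stress and cell death 6 lower and 1 higher (adjusted p = 1.48e-07, 1.22e-05 and 1.28e-08, each with an adjusted p = 0.0744 with an estimated correlation). The HIF pathway list had 5 lower and 1 higher of 11 (adjusted p = 0.00605, and adjusted p = 0.426 with an estimated correlation), and the interferon list 2 higher of 16 (adjusted p = 0.0258, and adjusted p = 0.544 with an estimated correlation). The S phase list had 2 higher and 1 lower, the mitosis list 2 lower and the heat shock list 1 higher (adjusted p = 0.00298, 0.0165 and 0.0165, and 0.532, 0.544 and 0.426 with an estimated correlation). The estrogen list (adjusted p = 0.0534) passed with the block (adjusted p = 0.0298, and adjusted p = 0.235 with an estimated correlation), and the remaining lists did not pass. With the block 16 dioxygenases, 9 angiogenic genes and 12 genes for pH, stress and cell death were lower, while 11 S phase genes were higher and 2 lower, and 10 ribosome biogenesis genes higher and 2 lower. Also with the block, 6 mitosis genes were lower, 6 interferon genes higher and 1 lower, 5 heat shock genes higher and 1 lower, and 3 estrogen response genes higher and 5 lower. In the integrated stress list 6 were then higher and 2 lower, and in oxidative phosphorylation 9 higher and 4 lower. Without the arrays numbered 1, 11 genes for pH, stress and cell death were lower, 6 interferon genes higher and 1 lower, 4 S phase genes higher and 2 lower, and 3 heat shock genes higher. In that fit the mitosis list did not pass (adjusted p = 0.0564), the estrogen list did (adjusted p = 0.0326, and adjusted p = 0.393 with an estimated correlation), and glycolysis and ribosome biogenesis did not with an estimated correlation (adjusted p = 0.174 and 0.189). A total of 423 genes were higher and 340 lower, 3094 with the replicate block and 1161 without the arrays numbered 1. Without HIF1 siRNA 1, HIF1 siRNA 3, HIF2 siRNA 1, HIF2 siRNA 2 or HIF2 siRNA 3 the count was 486, 376, 344, 382 and 357. The interaction, which asks whether the joint change differs from the sum of the single changes, called no gene in limma, and 2 with the block. Without the block 260 of 12145 genes had an unadjusted p under 0.05, again fewer than a share of 0.05. Its lists held no called gene. Interferon genes had the lowest list p of the interaction, with a median of 0.48 (adjusted p = 8.09e-05, and adjusted p = 0.803 with an estimated correlation). The glycolysis list and the list for pH, stress and cell death had medians of -0.11 and -0.29, an adjusted p of 0.0267 each, 0.803 with an estimated correlation, and 0.0868 and 0.0501 with the block. Without the arrays numbered 1 the angiogenic (adjusted p = 0.00252, against 0.128) and HIF pathway lists (adjusted p = 0.0283, against 0.42) passed for the interaction, each with an adjusted p = 0.717 with an estimated correlation.

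To ask how far the hypoxic changes depend on HIF, the 260 genes raised and 141 lowered by at least 1 log2 unit in hypoxia on U133A were followed in the transfected hypoxic cells on U133 Plus 2, which are other samples. Of the raised genes 100 (38.5%) fell with HIF1 siRNA, none with HIF2 siRNA in limma (none rose, and the list median was -0.01) and 137 (52.7%) with HIF12 siRNA, against 2.2%, 0% and 2.7% of the other genes. The list medians were -0.71 with HIF1 siRNA (adjusted p = 0.00213 with an estimated correlation) and -0.97 with HIF12 siRNA (adjusted p = 0.000803), against an adjusted p of 0.541 with HIF2 siRNA. With the fixed correlation the HIF2 siRNA value was 0.0747, and 0.0279 with the block, where the estimated correlation gave 0.597. With the replicate block 68.8% fell with HIF1 siRNA and 81.5% with HIF12 siRNA, against 10.3% and 12.3% of the other genes in that fit. Of the lowered genes 62 (44.0%) rose with HIF1 siRNA, none with HIF2 siRNA (median 0.07, adjusted p = 0.0123, and adjusted p = 0.541 with an estimated correlation) and 60 (42.6%) with HIF12 siRNA. With the block 78.7% and 78.0% rose with HIF1 and HIF12 siRNA. Of the other genes 5% and 4% rose without the block, and 18.9% and 15.5% with it. The raised genes that fell most with HIF1 siRNA were GJA1, LOX, TMEM45A, IGFBP3 and FAM13A (6.24-fold, -2.64 ± 0.56). With HIF12 siRNA they were FAM13A (24.0-fold, -4.58 ± 0.56), GJA1, TMEM45A, IGFBP3 and EPAS1, itself a target of this siRNA. Some raised genes did not pass with HIF12 siRNA. VLDLR, raised 12.7-fold, had a value of -1.74 ± 0.72 (adjusted p = 0.183, and 0.00129 with the block). The inhibin subunit INHA, raised 12.6-fold, had -0.24 ± 0.18 (adjusted p = 0.5). The scaffold protein gene AKAP12, raised 11.4-fold, had -1.36 ± 1.08 (adjusted p = 0.532, and 0.00233 with the block), and DPYSL4, raised 9.26-fold, -2.28 ± 0.65 (adjusted p = 0.0532, and 2e-04 with the block). The matrix protein gene TGFBI, raised 8.09-fold, had -0.55 ± 0.53 (adjusted p = 0.627, and 0.0492 with the block). On Illumina INHA (-0.56, adjusted p = 0.00134), AKAP12 (-0.99, adjusted p = 0.00803) and DPYSL4 (-0.67, adjusted p = 0.000221) fell with HIF12 siRNA, and VLDLR (-0.17, adjusted p = 0.46) and TGFBI (-0.32, adjusted p = 0.425) did not pass.

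Compared directly, 97 of the raised genes (37.3%) were lower and 2 higher with HIF1 than with HIF2 siRNA (adjusted p = 0.00338 with an estimated correlation). Of the other genes 2.8% were lower and 3.9% higher. On Illumina 101 of 244 raised genes (41.4%) were lower and 36 (14.8%) higher (adjusted p = 2.58e-06, and adjusted p = 0.343 with an estimated correlation). There 16.5% of the other genes were lower and 15.2% higher. The raised genes lay lower with HIF12 than with HIF1 siRNA on U133 Plus 2 (median -0.20, 1 gene called, adjusted p = 3.14e-12, and adjusted p = 0.0698 with an estimated correlation). They did not on Illumina (median 0.03, adjusted p = 0.955). EPAS1, a target of HIF2 and HIF12 siRNA, is itself among the raised genes and so enters both comparisons. Against OF on U133 Plus 2 it changed by 0.26 with HIF1 siRNA, -4.05 with HIF2 siRNA and -3.92 with HIF12 siRNA. Genes raised by DMOG behaved in the same test as follows. Of 259 raised genes 82 (31.7%) fell with HIF1 siRNA, none with HIF2 siRNA and 124 (47.9%) with HIF12 siRNA, and of 101 lowered genes 32, none and 28 rose. With the block 158 and 199 of the raised genes fell with HIF1 and HIF12 siRNA, and 70 and 67 of the lowered genes rose. Of the other genes 2.5% and 2.8% fell without the block, and 10.5% and 12.4% with it. The shares of other genes that rose were 5.4% and 4.5%, and 19.3% and 16% with the block. The counts depended on single sets of arrays. Without the arrays numbered 2 or 3, 6.9% and 0% of hypoxia-raised genes fell with HIF1 siRNA, and 20% and 6.5% with HIF12 siRNA.

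**Figure D3:**
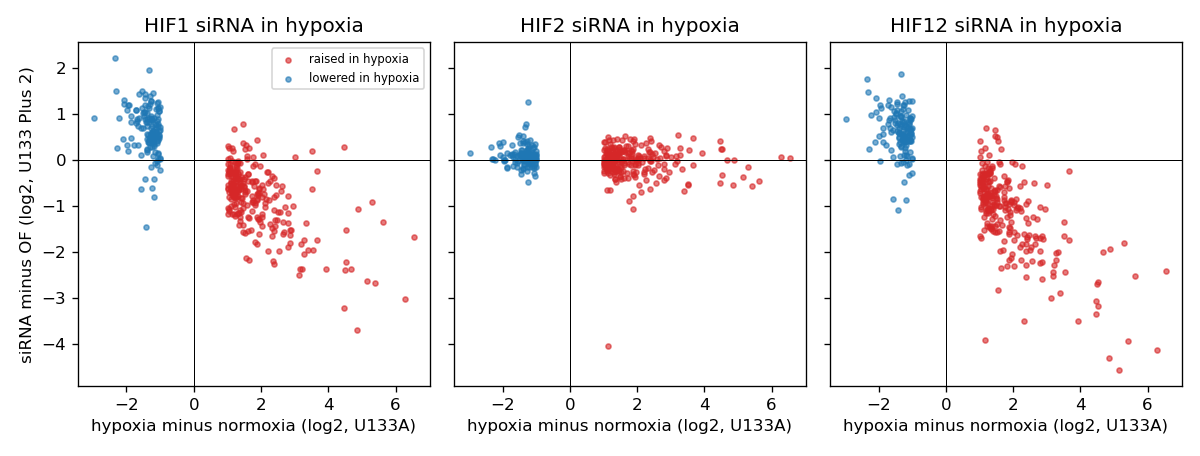
Change in hypoxia on U133A (horizontal axis, log2) against the change with HIF1, HIF2 and HIF12 siRNA on U133 Plus 2 (vertical axes, log2), 1 point per gene. Only the 260 genes raised and 141 lowered by at least 1 log2 unit in hypoxia are drawn. Across all 7298 genes tested in hypoxia, most of them not drawn and not independent replicates, the correlation was -0.588, -0.127 and -0.633.

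The Illumina arrays repeated these comparisons with another probe technology, on the same samples 2 and 3 for hypoxia and DMOG and on new samples for the siRNA groups. ADM rose 19.3-fold in hypoxia, NDRG1 with 4.99 log2 units and FOS with 4.39. In hypoxia 1241 genes were higher and 1471 lower of 11175, and with DMOG 1390 and 1764. Without hypoxia 3 the count in hypoxia was 1583, and without DMOG 2 the count with DMOG was 2041. Of the 536 genes called in hypoxia on U133A and tested on Illumina, 533 had the same sign and 460 were called in the same direction, and with DMOG 495 of 497 and 450. Glycolysis genes rose in 23 of 25 cases in hypoxia (adjusted p = 0.000261 with an estimated correlation) and 24 of 25 with DMOG, where 1 fell (adjusted p = 0.000333). Of 18 ribosome biogenesis genes 11 fell in hypoxia (adjusted p = 0.0503 with an estimated correlation) and 12 with DMOG (adjusted p = 0.0581). Of 26 S phase genes 2 fell in hypoxia and 14 with DMOG (adjusted p = 0.242 and 0.0261 with an estimated correlation). None of the 4 leukocyte and endothelial markers tested was called in any Illumina comparison.

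With siRNA on Illumina, 997 genes were higher and 1078 lower with HIF1 siRNA, 864 and 776 with HIF2 siRNA, and 1133 and 1010 with HIF12 siRNA. Glycolysis genes fell in 19 of 25 cases with HIF1 siRNA (camera adjusted p = 1.71e-19, and adjusted p = 0.00121 with an estimated correlation), 2 of 25 with HIF2 siRNA (0.336 and 0.664) and 15 of 25 with HIF12 siRNA (1.57e-10 and 0.0155). The dioxygenase list had 9 of 23 lower with HIF1 siRNA, the angiogenic list 7 of 14 lower and 1 higher and the list for pH, stress and cell death 11 of 17 lower and 1 higher (adjusted p = 5.45e-06, 5.45e-06 and 2.28e-10, and 0.00754, 0.0282 and 0.0615 with an estimated correlation). With HIF12 siRNA these lists had 6, 6 and 12 lower and 1, 0 and 1 higher (adjusted p = 0.0548, 0.000129 and 7.92e-08, and 0.258, 0.133 and 0.237 with an estimated correlation). With HIF2 siRNA 1, 3 and 1 were lower and 2, 0 and 0 higher (adjusted p = 0.706, 0.479 and 0.0369, and 0.809, 0.664 and 0.664 with an estimated correlation). In the fit with the block the list for pH, stress and cell death passed with an estimated correlation as well (adjusted p = 0.000728 with HIF1 siRNA and 0.00281 with HIF12 siRNA). Of 26 S phase genes 10 fell with HIF1 siRNA and of 24 mitosis genes 9 fell (adjusted p = 0.00754 each with an estimated correlation), or 17 and 11 with the block, where on U133 Plus 2 the called genes were mostly higher. ENO2 fell with -2.43 (HIF1 siRNA, adjusted p = 1.01e-11) and -1.42 (HIF12 siRNA, adjusted p = 1.34e-08), and IGFBP3 with -1.34 and -2.65. Of 244 hypoxia-raised genes found, 107 (43.9%) fell with HIF1 siRNA, 45 (18.4%) with HIF2 siRNA and 122 (50%) with HIF12 siRNA, against 11.3%, 8.8% and 10.5% of the other genes. The adjusted p-values were 5.21e-19, 0.000127 and 1.31e-23, and 0.0399, 0.272 and 0.0219 with an estimated correlation. Of 136 hypoxia-lowered genes 47 (34.6%), 42 (30.9%) and 62 (45.6%) rose, against 10.3%, 9.2% and 11.9% of the other genes (adjusted p = 8.74e-11, 9.36e-08 and 1.03e-13, and 0.0529, 0.19 and 0.0302 with an estimated correlation). With the block the value of 0.0529 for HIF1 siRNA was 0.000936. For HIF2 siRNA the sample numbers did not pair the arrays (lowest same-number correlation 0.03). With the block there, camera with an estimated correlation gave an adjusted p = 0.00788 for raised and 0.00502 for lowered genes. Of the genes called on U133 Plus 2 with HIF1 siRNA and tested on Illumina, 602 of 751 had the same sign, 295 were called in the same direction and 19 in the opposite one. With HIF12 siRNA these numbers were 632 of 751, 344 and 19, and with HIF2 siRNA 3 of 3, 1 and 0. With the block on U133 Plus 2, 786 were called in the same and 104 in opposite directions with HIF1 siRNA, and 839 and 86 with HIF12 siRNA. Between HIF1 and HIF12 siRNA 884 genes were called in the same and 46 in opposite directions, and between HIF2 and HIF12 siRNA 1208 and 9 (independent lists would share 101.1 higher and 97.4 lower genes, and 87.6 and 70.1). For these pairs the covariance of the changes was 0.061 and 0.08, against 0.01 in simulations with simulated shared controls. The r was 0.556 and 0.809, against 0.499 and 0.502 there. The 3 OF arrays could not be split into such parts here either, so part of the excess of shared genes over independent lists can come from them.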

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

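The tests of other divisions of the samples, of array brightness and of the response to hypoxia were chosen before their results were seen, and all other tests of this part after. Some probes that carry no single gene name, and so stand in no comparison of the report, passed the same threshold: 61 in hypoxia and 47 with DMOG on U133A, and 86 with HIF1 siRNA, 111 with HIF12 siRNA and 77 between HIF1 and HIF2 siRNA on U133 Plus 2. On Illumina these were 907 in hypoxia, 768 with DMOG, 281 with HIF1 siRNA, 218 with HIF2 siRNA and 291 with HIF12 siRNA.

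In the 2 sets of transfected samples 19 genes were called in opposite directions with HIF1 siRNA, 11 of them higher on U133 Plus 2, and 19 with HIF12 siRNA, 15 of them higher on U133 Plus 2. With the replicate block on U133 Plus 2 these numbers were 104 and 86. The difference itself was not tested. With HIF1 siRNA MKI67 had 0.62 on U133 Plus 2 and -0.99 on Illumina, and NAB1 -1.89 and 0.54. With HIF12 siRNA AKR1C1 had 1.27 and -1.13, and RABGAP1 -1.61 and 0.34. These 4 genes were chosen after their values were seen.

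HIF2 siRNA changed 3 genes on U133 Plus 2, and 864 higher and 776 lower genes were found on Illumina, in different samples. Over the genes called on Illumina, the U133 Plus 2 change rose with a slope of 0.128 per log2 unit (SE 0.009). For HIF1 siRNA the slope was 0.608 (SE 0.017). The HIF2 siRNA changes were thus smaller on U133 Plus 2, which speaks against larger spread between those arrays as the whole cause. The slopes alone do not exclude larger spread, since their SE count genes of the same arrays as independent. The genes were also chosen by their Illumina change. With the replicate number as a block the median SE on U133 Plus 2 was 0.137 (0.212 without it), against 0.128 on Illumina without a block. HIF2 siRNA then called 32 genes and HIF1 siRNA 3287 on U133 Plus 2. These values also argue against larger spread as the whole cause. A weak lowering of EPAS1 RNA in the U133 Plus 2 samples cannot account for the low count there, since the 95% interval of its change ended at -2.70. Illumina OF arrays standing apart would move HIF1 and HIF2 siRNA alike, and the slope of the HIF1 on the HIF2 siRNA change was 0.199 (SE 0.016), which speaks against this as the whole cause if the own effects of the siRNAs are unrelated. This test was chosen after a correlation of 0.205 and a covariance of 0.02 had been seen (0.5 and 0.01 in simulations with shared controls). Of the genes called with both siRNAs, 393 changed in the same and 154 in opposite directions. A shared part remains open, as does a difference in the cells or the siRNA.

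The 4 U133 Plus 2 arrays numbered 1 lay apart from the others in every group. With quantile normalization the lowest same-number correlation over all numbers was 0.514, against 0.518 as deposited. This cannot decide whether brightness left by the normalization played a part. A uniform shift in brightness does not alter a correlation across genes, and GCRMA already holds a quantile normalization. A stronger or weaker response to hypoxia in the cells numbered 1 would follow the hypoxic change, and the correlation was 0.041, with a median deviation of hypoxia-raised genes of -0.04. A difference between batches of cells or of array handling was not tested, since the labels give none.

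Hypoxia 1 and DMOG 1 had the highest beta-actin 3' to 5' ratios on U133A, 2.34 and 1.73 log2 units, while the GAPDH ratio stood apart only on hypoxia 1 (1.01, against 0.25 on DMOG 1 and 0.06 to 0.38 on the others). A single RNA quality profile would move the same genes on both, and their deviations correlated with -0.04, so it does not account for both arrays. A different profile on each array remains open, and no biological explanation was tested.

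With 10 divisions of 3 against 3 arrays, a share under 0.05 cannot be reached. The true division alone (1 of 10) gave as many called genes as were found for hypoxia, HIF1, HIF2 and HIF12 siRNA and HIF1 against HIF2 siRNA on Affymetrix arrays and for the 3 siRNA comparisons on Illumina, with 0 called genes as the highest other count. For DMOG it was also 1 of 10, with 1 as the highest other count, and for hypoxia against DMOG, where no gene was called, 10 of 10. For the interaction all 100 drawn divisions did, and the highest count, 1813, came from a division with all arrays that received HIF1A siRNA on one side.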

How the results depend on the processing

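The number of arrays limits the precision, and signal over background limits dim genes such as EPAS1 on Illumina. No named gene or list that passed in the report passed in the opposite direction under any alternative run for it. Of 182 called values of named genes 113 kept their call under all alternatives run for them. Every probe set, only the groups compared, the stricter adjusted p and the limit on the size of change were not run for named genes. Lists were rerun only with an estimated correlation, fry, no filter and the block, and without the arrays that stood apart. The separate Illumina siRNA samples were not among these alternatives. Leaving out single arrays weakened 252 of 1116 values of named genes, the mean of all probe sets 21 of 183, no filter 24 of 186, quantile normalization 5 of 186, and a constant prior variance 4 of 186. Of 213 list results, an estimated correlation weakened 64, fry weakened 31 and strengthened 17, no filter weakened 1 and strengthened 15, and the block weakened 3 and strengthened 5. Totals of called genes, and the shares of the hypoxia list that changed, stayed within 1.5 times with no filter, with the mean of all probe sets, with arrays centred on their median, and for the hypoxia list with no fold limit or matched by symbol. By direction, no filter left 146 genes lower in hypoxia (against 241), 126 lower with DMOG (against 210) and 341 higher with HIF1 siRNA (against 518). With no fold limit 95 and 94 of 241 hypoxia-lowered genes rose with HIF1 and HIF12 siRNA. The cause of the changes below was not tested, except that stricter thresholds leave fewer calls by construction. Leaving arrays out lowered the count in some fits and raised it in others, as for DMOG without DMOG 1 (965 against 532).

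With an adjusted p under 0.01, called genes numbered 209 in hypoxia, 231 with DMOG, 239, 0 and 298 with HIF1, HIF2 and HIF12 siRNA and 268 for HIF1 against HIF2 siRNA on Affymetrix arrays. On Illumina they numbered 1514, 1934, 1201, 895 and 1270 for hypoxia, DMOG, HIF1, HIF2 and HIF12 siRNA. With a change of at least 1 log2 unit there were 314 (HIF1 siRNA), 328 (HIF12 siRNA) and 316 (HIF1 against HIF2 siRNA) on U133 Plus 2, and 367, 484, 182, 101 and 177 on Illumina. Quantile normalization gave 861 genes in hypoxia, 926 with DMOG (48.1% of them higher, against 60.5%) and 2 between hypoxia and DMOG. With only the groups compared in the fit, 244, 0 and 240 genes were called with HIF1, HIF2 and HIF12 siRNA and 273 between HIF1 and HIF2 siRNA. Testing every probe set left 1 with HIF2 siRNA. The interaction had 1 called gene with a 60th percentile filter and 1 with a constant prior variance. Of genes raised at least 2 log2 units in hypoxia, 59.5% fell with HIF1 siRNA and 79.7% with HIF12 siRNA.

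Chosen after seeing the data, the fits without hypoxia 1 and DMOG 1 called 763 genes in hypoxia, 1427 with DMOG and 7 between them, and weakened 4 of 48 list results. Those without the 4 arrays numbered 1 called 1336 (HIF1 siRNA), 1362 (HIF12 siRNA) and 1161 genes (HIF1 against HIF2 siRNA). Illumina arrays called 899 genes between hypoxia and DMOG.

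Where sample numbers pair the U133 Plus 2 arrays, the block called 3287, 32 and 3127 genes with HIF1, HIF2 and HIF12 siRNA, 3094 between HIF1 and HIF2 siRNA and 2 for the interaction, and kept all genes called without it. Of hypoxia-raised genes 68.8%, 0.4% and 81.5% then fell, and of hypoxia-lowered genes 78.7%, 0.7% and 78% rose. Of the other genes 10.3%, 0.1% and 12.3% fell and 18.9%, 0.2% and 15.5% rose in that fit. On Illumina the paired comparisons had 2759 (HIF1 siRNA) and 2857 (HIF12 siRNA) called genes. Where numbers are only shared, the block called 442 genes in hypoxia, 425 with DMOG and 0 between them on U133A, 2408 with HIF2 siRNA on Illumina (where 75 of 244 hypoxia-raised genes then fell, against 45, and 51 of 136 hypoxia-lowered genes rose, against 42, with adjusted p = 0.00788 and 0.00502 with an estimated correlation), and 3524 and 3925 in hypoxia and DMOG on Illumina. Not every U133A array there correlated best with its own number. The same held for HIF12 siRNA against OF on U133 Plus 2, where same-number correlations were 0.518 to 0.788. How far the arrays numbered 1 alone produce these correlations was not tested. With the pairing of the 2 Illumina DMOG and normoxia samples crossed, 4161 genes were called.

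Leaving out 1 array at a time, called genes ranged from 287 to 395 in hypoxia, 280 to 965 with DMOG and 0 to 9 between them. They ranged from 322 to 594, 0 to 1 and 368 to 672 with HIF1, HIF2 and HIF12 siRNA, 344 to 610 between HIF1 and HIF2 siRNA and 0 to 1 for the interaction, with 1 without HIF12 siRNA 3. On Illumina they ranged from 1583 (without hypoxia 3) to 2151 in hypoxia and from 2041 (without DMOG 2) to 2344 with DMOG, where the lone array left in a group was assumed to vary like the other groups. For the hypoxia list all U133 Plus 2 arrays of a number were left out together, not single arrays. The share of hypoxia-raised genes that fell then ranged from 0% to 51.2% with HIF1 siRNA, 0% to 0.4% with HIF2 siRNA and 6.5% to 62.3% with HIF12 siRNA. The share of hypoxia-lowered genes that rose ranged from 0% to 53.9% with HIF1 siRNA, being 0% without the arrays numbered 2 and without those numbered 3. With HIF12 siRNA it ranged from 0.7% without those numbered 3 to 52.5%, with 4.3% without those numbered 2.

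Not run were the planned comparison of OF with hypoxia on Illumina with its alternatives, since the 2 sets were normalized separately, and offsets before the logarithm, since no value was 0 or below.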

Other observations

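Hypoxia and DMOG, which shared most of their called genes in the report, differed for 899 genes on Illumina (527 higher in hypoxia, 372 higher with DMOG), 53 of them by at least 1 log2 unit, a comparison chosen after seeing the data. The genes named in this paragraph and the next were chosen after their values were seen. CYP1A1, which encodes a xenobiotic-metabolizing cytochrome P450, read 6.51 log2 units in normoxia, 8.92 in hypoxia and 7.29 with DMOG (difference 1.63 ± 0.40, 3.1-fold, limma adjusted p = 0.0162). SCNN1A read 11.53, 11.51 and 10 (1.51 ± 0.21, adjusted p = 0.000312) and the chromatin reader ZMYND8 11.58, 12.66 and 11.21 (1.45 ± 0.12, adjusted p = 1.53e-06). Higher with DMOG were MALL (8.84, 9.73 and 11.45, difference -1.72 ± 0.15, adjusted p = 1.79e-06), the collagenase MMP13 (6.73, 7.39 and 8.81, -1.42 ± 0.15), the membrane fusion protein STX3 (10.08, 9.21 and 10.66, -1.45 ± 0.17) and the receptor adaptor GRB10 (7.71, 7.76 and 9.15, -1.39 ± 0.15). Of 544 such genes tested on U133A, 490 had the same sign there, in samples of which 2 of 3 per group are the same.

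With HIF1 siRNA on Illumina 10 of 26 S phase genes and 9 of 24 mitosis genes fell (list medians -0.34 and -0.27), where on U133 Plus 2 a single gene of each list was called, and higher. With the replicate block 17 and 11 fell on Illumina, while 12 S phase genes were higher and 2 lower, and 4 mitosis genes higher and 1 lower, on U133 Plus 2. FEN1 fell with -1.59 ± 0.13 (adjusted p = 4.28e-08), the replicative helicase subunit MCM2 with -0.71, MKI67 with -0.99 ± 0.14 (adjusted p = 3.2e-05) and the mitotic kinesin KIF20A with -0.83. Of 12 p53 targets 6 rose and 1 fell (camera adjusted p = 0.00949, and adjusted p = 0.222 with an estimated correlation), GDF15 with 0.84 and the cyclin-dependent kinase inhibitor CDKN1A with 0.58 ± 0.09 (adjusted p = 0.000148) among the risen. Of the interferon response genes under HIF2 siRNA, IFI6 had -1.45 (adjusted p = 1) on U133 Plus 2 and -1.07 ± 0.27 (adjusted p = 0.00926) on Illumina, and OAS1 -1.68 (adjusted p = 1, and 0.0244 with the replicate block) and -1.55 (adjusted p = 0.0687). The Illumina list median was -0.95, with 1 of 18 genes called (adjusted p = 0.000687, and adjusted p = 0.664 with an estimated correlation).

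The hypotheses tested here were formed after the report's values had been seen. The first was that EPAS1 siRNA lowers hypoxia-raised genes more when HIF1A is lowered too. The median interaction of these genes was -0.23 on U133 Plus 2 (p = 0.141 in camera with an estimated correlation, 199 of 260 genes below 0, 1 called) and 0.12 on Illumina (p = 0.232, 89 of 244 below 0, 21 called), so the data did not decide it. Both values are from the fit without the block, which was not run for this test. The other was that glycolysis genes lose a larger share of their hypoxic rise with HIF1 siRNA than other raised genes. The 12 raised glycolysis genes lost a median of 55.4% on U133 Plus 2 and the other 248 raised genes 44.4%, a difference of 11 points (permutation p = 0.279, two-sided), which does not decide it either. The share divides the log2 change in transfected cells by the log2 rise on U133A in other, untransfected cells, since the rise in transfected cells is not known. Over all raised genes the median share with HIF1 siRNA was 45.4% on U133 Plus 2 and 18.4% on Illumina. The Illumina share divides an Illumina change by a U133A rise. Over genes called in hypoxia on U133A, the Illumina change had a slope of 0.652 on the U133A change. The 2 shares are therefore not on a like scale.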
